A study of Mus musculus with 8 samples.

How the data were processed

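Gene expression was measured in granulocyte-macrophage progenitors (GMP) from 4 samples of mice lacking both Ssb1 and Ssb2 (DKO) and 4 samples of wild-type control mice, each hybridised in 1 colour to an Illumina BeadArray of the MouseRef-8 v2.0 design. Per the labels' protocols, RNA was extracted on RNeasy columns and treated with DNase, and biotinylated cRNA was made with the Illumina TotalPrep kit. GenomeStudio is named per the submitters' processing notes, without a version or a role, and other upstream steps are not given in the sources used here. The deposited non-normalized table holds 1 summarised bead intensity per probe and array on a linear scale, neither background-subtracted nor normalized, as read from its values. Beside each intensity, the deposited table gives a detection p-value per the file headers, and how the authors computed it is not given in the sources used here. The table also has 10 unnamed columns, which are empty. The authors' processed table holds log2 values that had been quantile-normalized and centred per probe, a scale found by setting it against the intensities and not stated in a header. The differences between arrays in the authors' log2 table followed those of quantile-normalized log2 intensities with r between 0.9992 and 0.9995 over probes and slopes between 0.962 and 0.968, and the column medians lay between -0.0044 and -0.0005. The centre of that table stays unknown, because the mean over the 8 arrays varied between probes with an SD of 0.26 on the log2 scale. It was used as an alternative only.

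All 25697 probes were read. The platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, and 23962 were matched by gene identifier to RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. No coordinates are given, because the array names no genome build, and the RefSeq table served only for names and for the order of neighbouring genes.

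The intensities were normalized with neqc of limma 3.58.1 in R 4.3.3, which corrects the background by normexp with negative controls inferred from the detection p-values, adds an offset of 16 and applies quantile normalization. Probes with a detection p-value under 0.05 on at least 4 of the 8 arrays were tested, which left 10856 probes, 613 of them without a symbol, and 7604 genes. The groups were compared with lmFit and eBayes of limma without covariates, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Differences are DKO minus control on the normalized log2 scale, with the moderated standard error (SE), and means are given with the SD over 4 arrays. A probe detected on 0 of the 4 arrays of a group has only a bound there, so its change is written as at least N-fold, from the brighter group's mean against the lowest signal among detected probes or the probe's own signal, whichever was higher on each array.

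Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, on 1 probe per gene, the tested probe with the highest mean over all arrays, with adjustment over 23 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Counts of list members are given after adjustment over all tested probes, and again adjusted over the list alone. Array measures were compared by exact two-sided permutation tests over the 70 relabellings, whose smallest possible p is 0.0286.

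The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Nabp1 and Nabp2 are always named. The 10 genes with the largest rise and the 10 with the largest fall are named among probes past the threshold that were detected on all 4 arrays of at least one group and showed no overlap between the groups, each gene by its probe with the largest change. Names that are only clone, locus or model numbers are passed over. From each list, up to 4 members with the smallest p are named. Genes named outside this rule are marked as chosen after their values were seen.

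The alternatives were no background correction, normexp without controls at an offset of 50, alignment of arrays by their medians in place of quantiles, the authors' processed values, no filter on dim probes, a filter at a detection p-value under 0.01 on all 8 arrays, a trended and robust variance, array weights, the replicate number as a block, a minimum change of 1.5-fold, and leaving out each array in turn. Leaving out 2 DKO arrays together was added after seeing the data. A block for the BeadChip was not run, since no slide is given for the arrays used here.

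The procedure was tested on simulated data for the comparison of DKO with control GMP, with the probes, means and spreads of the real arrays and 200 probes changed by known amounts. Over 10856 probes it recovered 64% of those changed 2-fold and 19% of those changed 1.5-fold, 5 of its 88 calls were false, and it made 0 calls when no probe was changed. The simulated probes varied independently and few were changed, while 22.7% of the tested probes passed the threshold in the real data. These shares therefore need not hold for the real comparison. Figures were drawn with matplotlib. The number of arrays, 4 per group, limits the precision of every value.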

Results

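Granulocyte-macrophage progenitors are the myeloid progenitors that give rise to granulocytes and monocytes. They were sorted as lineage-low, c-Kit-positive, Sca-1-negative cells with high CD34 and high CD16/32 surface levels from female C57BL/6 mice. The comparison asks how gene expression in these cells differs when Ssb1 and Ssb2, a pair of related single-stranded DNA binding proteins encoded by Nabp2 and Nabp1, are both lost. There were 4 DKO and 4 control arrays. The labels do not say that the samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

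The DKO arrays detected 9774, 9867, 11103 and 10831 probes, and the control arrays 11227, 11217, 11142 and 10740. The mean raw intensity was 533 ± 107 (SD, n = 4) in DKO and 643 ± 62.4 (SD, n = 4) in control, with the lowest value, 380, on DKO 1. Exact two-sided permutation tests of 5 such array measures gave p between 0.0571 and 0.257, and between 0.179 and 0.257 after adjustment over the 5 measures. Correlations of normalized values over probes ranged from 0.966 to 0.992 within a group and from 0.949 to 0.975 between groups. The first principal component, with 52.7% of the variance, placed all 4 DKO arrays on one side and all 4 control arrays on the other. The smallest mean absolute log2 difference between any 2 arrays of a group was 0.21, so no array was a copy of another.

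Nabp2, which encodes Ssb1, fell in DKO GMP. Its brighter probe, ILMN_2837156, measured 7.14 ± 0.49 (SD, n = 4) in DKO and 8.82 ± 0.46 (SD, n = 4) in control, 3.20-fold lower (log2 difference -1.68, SE 0.27, limma adjusted p = 0.00198). The DKO arrays read 7.27, 7.43, 6.42 and 7.45, below the control arrays at 8.96, 9.09, 8.13 and 9.10. This brighter probe was detected on all 4 DKO arrays, so its signal was reduced there and not absent. The log2 difference was -1.08 with no background correction and -1.09 with the authors' processed values, past the threshold in both. The dimmer Nabp2 probe, ILMN_2593852, differed by -0.41 (SE 0.30, limma adjusted p = 0.355) and did not pass the threshold, and its difference was -0.82 and past the threshold when arrays were aligned by medians and -0.80 and past it with array weights. The single Nabp1 probe was detected on 0 of the 8 arrays and checks nothing about the loss of Ssb2. Where the probes lie relative to the deleted parts of the genes is not known here.

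Between DKO and control GMP, 1125 probes rose and 1344 fell, 22.7% of those tested. They stood for 898 genes with a higher probe and 1139 with a lower one, 4 of them with both. At a change of at least 2-fold there were 222 higher and 351 lower probes, against 67 and 97 with no background correction, 66 and 97 with the authors' processed values, 104 and 166 with normexp without controls, 94 and 1150 with arrays aligned by medians and 153 and 192 with probes detected on all arrays only. The values of the 2 groups did not overlap for 91.8% of the probes past the threshold and for 27.6% of all tested probes, where chance gives 2.86%. Of the 1941 genes with several tested probes, 678 had a probe past the threshold, and in 472 of these another probe was not past it or went the other way. The share of higher probes, 45.6%, depended on scaling. With arrays aligned by medians, the median of all tested probes moved to -0.40 on the log2 scale, and 148 probes were higher and 2335 lower, 5.96% higher. Without control 2 the counts were 680 higher and 869 lower, and without control 1 they were 745 and 956.

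After neqc normalization, the largest rises were led by interferon-induced genes. Oas2, a sensor of double-stranded RNA, was 10.7-fold higher (log2 difference 3.42, SE 0.23, limma adjusted p = 1.61e-05, n = 4 per group). Rsad2, which encodes the antiviral enzyme viperin, was 10.6-fold higher, the ubiquitin-like modifier Isg15 9.19-fold and Usp18, the protease that removes it, 8.99-fold. On the control arrays, Oas2 and Rsad2 were detected on 3 of 4 and Phlda3 on 2 of 4. Lcn2, which encodes the iron-sequestering granule protein lipocalin 2, rose 8.89-fold (log2 difference 3.15, SE 0.19). Degs2, a sphingolipid desaturase, and the forkhead gene Foxd4 were not above background on any control array and were at least 7.16-fold and at least 5.20-fold higher. The p53 target Phlda3 rose 7.56-fold, the DNA methyltransferase cofactor Dnmt3l 7.45-fold and Dgat2, an enzyme of triglyceride synthesis, 6.99-fold. With the authors' processed values the log2 difference of Oas2 was 1.61, that of Rsad2 1.74 and that of Usp18 2.35. Lcn2 and Dgat2 were not among the genes whose fold was over 1.5 times smaller there, so the order of the rises depended on the processing.

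After neqc normalization, transcription factors of the monocyte lineage led the falls. Irf8, a factor required for monocyte and dendritic cell fate, was 12.9-fold lower (log2 difference -3.69, SE 0.35, limma adjusted p = 0.000112, n = 4 per group), and Klf4, which promotes monocyte differentiation, was 6.48-fold lower. The lysosomal protease gene Ctsh fell 6.45-fold, Rdm1 6.39-fold, Grcc10 6.39-fold, the integrin gene Itgb7 5.14-fold, Cpq 4.90-fold, the lysozyme gene Lyz2 4.87-fold and Fbxw4 4.69-fold. Klf4 and Itgb7 were each detected on 1 of the 4 DKO arrays. One probe of Plxdc1, ILMN_2827162, was not above background on any DKO array and was at least 3.25-fold lower, while its other probe, detected on 1 of the 4 DKO arrays, was 1.31-fold lower and did not pass (limma adjusted p = 0.0849). With the authors' processed values the log2 difference of Irf8 was -2.76, that of Klf4 -1.01 and that of Cpq -1.09, so Klf4 no longer ranked above Cpq. Ctsh, Grcc10 and Lyz2 were not among the genes whose fold was over 1.5 times smaller there.

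**Figure D1:**
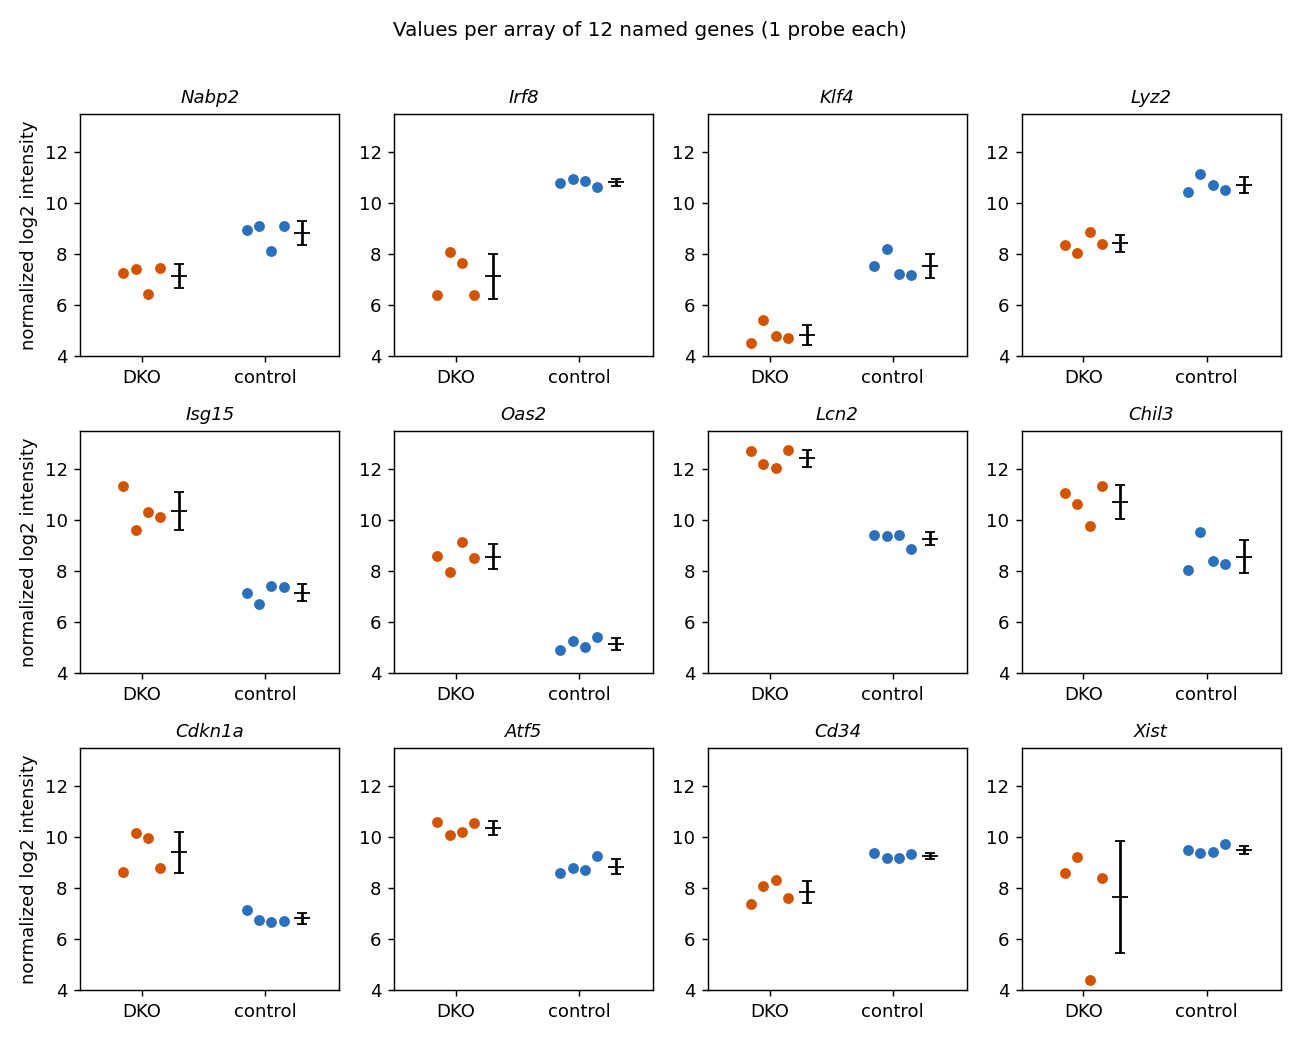
Normalized log2 intensity (vertical axis) of 12 named genes on each of 4 DKO and 4 control arrays, 1 point per array in replicate order, with the mean and SD of each group beside the points. Irf8 averaged 7.12 in DKO and 10.81 in control, and Xist was at 4.39 on DKO 3 and between 8.40 and 9.20 on the other DKO arrays.

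Of 52 measured interferon response genes, 28 rose, 7 fell and 17 did not pass the threshold. Adjusted over the list alone, 33 were higher and 8 lower. The list was higher than other genes (median log2 difference 0.64, camera adjusted p = 2.31e-07), and adjusted p = 0.535 with an estimated correlation. With arrays aligned by medians 15 rose and 10 fell and the median was 0.13, and it was 0.31 with no background correction, 0.32 with the authors' processed values, 0.40 with normexp without controls and 0.40 with no filter on dim probes, with camera adjusted p of at most 1.09e-06 in these 5 settings. Besides Oas2 and Rsad2, the membrane antiviral gene Ifitm3 rose 3.76-fold and Samd9l 3.75-fold, with log2 differences of 1.91 (SE 0.13) and 1.91 (SE 0.14). The 7 members that fell, named after their values were seen, were Ly6e, Ifi27l2a, the class I antigen presentation genes H2-D1, B2m, Psmb9 and Tapbp, and the transcription factor Irf1, with log2 differences from -1.82 to -0.48.

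Of 30 measured members of the Atf4 and unfolded protein list, 14 rose, 1 fell and 15 did not pass. The counts adjusted over the list alone were 16 higher and 1 lower. The median log2 difference was 0.47 (camera adjusted p = 6.69e-07, and adjusted p = 0.463 with an estimated correlation). With arrays aligned by medians 3 rose and 1 fell, and the median was 0.20 (adjusted p = 3.18e-08). The cystine transporter Slc7a11 was not above background on any control array and was at least 2.42-fold higher. The transcription factor Atf5 rose 2.88-fold, the glutathione-degrading enzyme gene Chac1 2.61-fold and the mitochondrial folate enzyme gene Mthfd2 2.26-fold.

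Of 27 measured p53 targets, 6 rose, 2 fell and 19 did not pass. Adjusted over the list alone, 8 were higher and 2 lower. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 5.98-fold (log2 difference 2.58, SE 0.32, limma adjusted p = 0.000473), and Mdm2, the ubiquitin ligase that targets p53, rose 1.69-fold, while Sesn1 fell 2.42-fold. The list had a median log2 difference of 0.29 (camera adjusted p = 0.0202, and adjusted p = 0.569 with an estimated correlation). Its call was lost with probes detected on all arrays only (adjusted p = 0.128) and by fry (adjusted p = 0.0565). Without DKO 3 the median was 0.15 (adjusted p = 0.0485), and 1 member fell rather than 2 without DKO 1, DKO 3, DKO 4, control 1, control 2 or control 3. With arrays aligned by medians 2 p53 targets rose and 4 fell, and the median was 0.018 (adjusted p = 0.00125). The median was 0.19 with no background correction, with normexp without controls and with the authors' processed values, and 0.18 with no filter on dim probes, where 1 fell, while 10 rose with array weights.

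Of 37 measured ribosome biogenesis genes, 9 rose, 1 fell and 27 did not pass. The counts adjusted over the list alone were 12 higher and 2 lower. Noc3l rose 1.91-fold, Mrto4 1.88-fold and Ebna1bp2 1.73-fold by its brightest probe, whose 2 other probes did not pass, and Pes1, a factor of large subunit maturation, fell 2.26-fold. Without control 1 the number that rose was 5 and without control 2 it was 4, and 2 fell without DKO 3. The list's median log2 difference was 0.20 (camera adjusted p = 0.00241, and adjusted p = 0.569 with an estimated correlation), and it turned to -0.08 with arrays aligned by medians, where 0 rose and 2 fell and the median of all tested probes was -0.40. The number that rose was 14 with no background correction, 15 with the authors' processed values and 14 with array weights. Among 55 ribosomal protein genes, 0 rose and 2 fell, and adjusted over the list alone 0 and 1. Rpl22 fell 2.86-fold (log2 difference -1.52, SE 0.17). Rpl29 fell 1.30-fold by one probe, while its other probe was 1.25-fold higher and did not pass. Leaving out any 1 of the 8 arrays ended the call of Rpl29 (adjusted p from 0.0524 to 0.107) and left 1 ribosomal protein gene lower, and 2 rose without DKO 2 and 1 without DKO 4. Rpl13a and Rps15 differed by 0.38 and -0.37, and Rpl13a passed without DKO 4 (adjusted p = 0.0411). The ribosomal protein list did not pass (camera adjusted p = 0.682), though it did with arrays aligned by medians (adjusted p = 8.42e-06), where 1 fell. Of the ribosomal protein genes 3 rose and 4 fell with no background correction and with a trended and robust variance, 4 rose and 4 fell with the authors' processed values, and 1 rose with normexp without controls and with array weights.

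Of 23 measured markers of the monocyte, macrophage and dendritic lineages, 15 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone. Besides Irf8 and Klf4, the protease gene Ctss fell 3.56-fold and Adgre1, which encodes the macrophage antigen F4/80, 4.33-fold, with Ctss detected on 1 and Adgre1 on 2 of the 4 DKO arrays. The 3 that rose, named after their values were seen, were Id2, the interferon-induced Bst2, and Apobr, with log2 differences of 1.39, 0.99 and 0.88. The list's median log2 difference was -1.04, or -0.91 with 3 members at their bounds (camera adjusted p = 4.75e-05, and adjusted p = 0.463 with an estimated correlation). With probes detected on all arrays only, 12 members were left, 6 fell, the median was -0.68 and the call was lost (adjusted p = 0.154). The median was -0.41 with no background correction, -0.42 with the authors' processed values and -0.62 with normexp without controls, and 1 member rose with arrays aligned by medians.

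Of 13 measured late neutrophil genes, 6 rose, 0 fell and 7 did not pass. Adjusted over the list alone, 6 were higher and 1 lower. Besides Lcn2, the chitinase-like gene Chil3 rose 4.42-fold and the annexin gene Anxa1 2.13-fold, and the cystatin gene Stfa1 was not above background on any control array and at least 1.96-fold higher. Abundant transcripts of mature neutrophils went both ways. S100a8 differed by -0.043 (SE 0.12), Camp by -0.40 (SE 0.40), Ltf by -0.38 (SE 0.28) and Ngp by 0.98 (SE 0.48), none of them past the threshold, and S100a9 rose 1.58-fold. The list's median log2 difference was 0.70 (camera adjusted p = 0.00473, and adjusted p = 0.569 with an estimated correlation). Its call was lost with array weights (adjusted p = 0.0541) and with probes detected on all arrays only (adjusted p = 0.0751). Without DKO 3 the median was 1.08, and 1 member fell without DKO 2. Over the 25 members on the array, with no filter on dim probes, the median was 0.16, and it was 0.35 with array weights and 0.47 with no background correction. With array weights, no background correction, normexp without controls, the authors' processed values, a trended and robust variance or probes detected on all arrays only, 1 member fell.

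The primary granule and GMP genes went both ways. Of 30 measured, 2 rose, 8 fell and 20 did not pass, and adjusted over the list alone 3 were higher and 8 lower. Dmkn rose 2.52-fold, while the adaptor gene Tyrobp fell 3.38-fold, the ficolin gene Fcnb 3.08-fold and Csf2ra, a subunit of the GM-CSF receptor, by 0.68 on the log2 scale. The granule genes Mpo, Elane, Prtn3 and Ctsg, chosen after their values were seen, had log2 differences of 0.19, 0.03, 0.11 and 0.05 and did not pass. The number that fell was 5 without control 1 and 5 without control 2, and 5 rose with no background correction, 4 with the authors' processed values and 1 with arrays aligned by medians. The list did not pass (camera adjusted p = 0.968), and its median of 0.08 differed in sign from its mean of -0.08 and its test.

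Of 10 measured stem and multipotent progenitor markers, 0 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone. Cd34, which encodes one of the surface markers used in the sort, fell 2.68-fold (log2 difference -1.42, SE 0.20, limma adjusted p = 0.000858), Cd27 3.53-fold, Txnip, a regulator of redox state, 2.15-fold and Tgm2 1.62-fold. The list's median was -0.76 (camera adjusted p = 0.0374, and adjusted p = 0.569 with an estimated correlation). The call was lost without DKO 4 (adjusted p = 0.108), without control 1 (0.0541), without control 4 (0.0535), with arrays aligned by medians (0.0537) and with no filter on dim probes (0.169, median -0.032). It was also lost with the replicate number as a block (camera adjusted p = 0.0821). The median was -0.35 with no background correction and with the authors' processed values, and -0.50 with normexp without controls.

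Of 10 measured heme synthesis and globin genes, 0 rose, 5 fell and 5 did not pass. Adjusted over the list alone, 0 were higher and 8 lower. The erythroid membrane genes Slc4a1, Ank1 and Kel and the receptor gene Epor were not above background on any DKO array, with bounds of at least 1.44-fold, 1.14-fold, 1.11-fold and 1.06-fold lower. The list's median was -0.70, or -0.49 with 4 members at their bounds (camera adjusted p = 0.00241, and adjusted p = 0.569 with an estimated correlation), and the call was lost with probes detected on all arrays only (adjusted p = 0.117). The number that fell was 1 without control 2, 2 without DKO 4 and 3 without control 3, and it was 9 with arrays aligned by medians, 8 with array weights, 3 with no filter on dim probes and 3 with probes detected on all arrays only. The median was -0.26 with no background correction, -0.27 with the authors' processed values, -0.41 with normexp without controls, -0.38 with no filter on dim probes and -1.13 with arrays aligned by medians. Epor lost its call without DKO 3, DKO 4, control 2 or control 3 (adjusted p from 0.0523 to 0.0824), Kel without DKO 4 (0.0627) or control 2 (0.0656) and Ank1 without control 2 (0.0623).

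Markers of other cell types did not pass as lists. Of 10 megakaryocyte and platelet genes, Clec1b rose 1.75-fold and Cd9 fell 1.67-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.827), and Gp9 and Treml1 differed by -0.41 and 0.53. Clec1b lost its call without control 1 (adjusted p = 0.0579) or control 4 (0.0558) and Cd9 without control 2 (0.0552) or control 3 (0.0520), while Gp9 passed without control 4 (0.0445), where 2 of the list fell. Of 15 basophil, mast cell and eosinophil genes, the histidine decarboxylase gene Hdc fell 2.56-fold and 14 did not pass, and adjusted over the list alone 1 was lower (camera adjusted p = 0.35, and 0.0228 without DKO 3). Ccl3, Cpa3 and Gata2 differed by -0.68, -1.17 and -0.90, and another Cpa3 probe passed. Without DKO 3, Ccl3, Cpa3 and Gata2 passed (adjusted p = 0.0256, 0.0115 and 0.0399) and 4 of the list fell, and without DKO 2 Cpa3 passed (0.0460) and 2 fell. Of 6 lymphoid genes, Thy1 rose 2.80-fold, Cd79b fell 1.70-fold and Rag1, not above background on any DKO array, was at least 1.02-fold lower. Adjusted over the list alone, 1 was higher and 3 lower (camera adjusted p = 0.454), and Vpreb1 differed by -0.76. Vpreb1 passed without DKO 3 (adjusted p = 0.0293), and without control 2 Rag1 did not pass (0.0516), which left 1 lower. In the check of sex-linked genes, 2 were measured and 0 passed, also adjusted over the list alone (camera adjusted p = 0.968). Xist, the RNA that coats the inactive X chromosome, differed by -1.86 (SE 0.83) with 1 DKO array below detection, and Uty by 0.23. Without DKO 3, that array, Xist differed by -0.78 by the same probe, ILMN_3022688, and passed (adjusted p = 0.0233). The other Xist probe, ILMN_3123341, read 8.04, 8.44 and 7.56 on DKO 1, DKO 2 and DKO 4 with all arrays normalized together. These values overlapped the 7.97 to 8.47 of the control arrays. After alignment of arrays by medians, 0 megakaryocyte genes rose and 2 fell, 4 basophil genes fell and 1 sex-linked gene fell. With no background correction and with the authors' processed values 0 megakaryocyte genes rose and 1 lymphoid gene fell.

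Cell cycle and DNA repair genes did not pass as lists. Of 46 DNA replication genes, 4 rose and 4 fell, with the same counts adjusted over the list alone. The cyclin genes Ccne2 and Ccne1 rose 2.37-fold and 2.01-fold and Rrm2, a subunit of ribonucleotide reductase, 1.79-fold, while the DNA ligase gene Lig1 fell 1.68-fold by its brightest probe, whose 3 other probes did not pass. Only 2 of this list fell without control 1 or without control 2. The list did not pass (camera adjusted p = 0.827), and its median of -0.01 differed in sign from its mean of 0.03 and its test. Of 35 mitosis genes, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.605). The mitotic kinase genes Plk1 and Aurka each rose by 0.58 on the log2 scale, Cdc25b fell 1.57-fold and Nusap1 1.44-fold. Without control 1 or control 2 the number that rose was 1, and Plk1 did not pass (adjusted p = 0.0513 and 0.0535). Of 39 repair and checkpoint genes, 2 rose and 2 fell, and adjusted over the list alone 0 and 1 (camera adjusted p = 0.682). Brip1 fell 1.63-fold and Fanci 1.68-fold, Lig4 rose 1.45-fold, and Xrcc4 rose 1.40-fold but turned to -0.059 on the log2 scale with arrays aligned by medians. Fanci lost its call without DKO 1, DKO 2 or any 1 control array (adjusted p from 0.0614 to 0.0896), Lig4 without DKO 1, DKO 3, DKO 4, control 2 or control 4 (0.0531 to 0.124) and Xrcc4 without DKO 1, DKO 4, control 1, control 2 or control 3 (0.0543 to 0.0841). Of the repair genes, 0 rose without DKO 1, DKO 4 or control 2 and 1 without control 3, and 1 fell without DKO 2, control 1, control 2 or control 4. Aligned by medians, the arrays gave 1 replication gene that rose and 8 that fell, 0 mitosis genes that rose, and 0 repair genes that rose and 9 that fell. With no background correction and with the authors' processed values 7 replication genes rose, 1 mitosis gene fell, and 4 repair genes rose and 1 fell. With array weights 5 mitosis genes rose.

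Of 12 genes of the SOSS and Integrator complexes, in which Nabp1 and Nabp2 act, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.588). The one that fell was Nabp2 itself. Ints13 rose 1.55-fold by its brightest probe, whose 2 other probes did not pass, Ints5 rose 1.39-fold but turned to -0.039 on the log2 scale with arrays aligned by medians, and Ints14 differed by 0.38. Ints5 lost its call without DKO 2, DKO 4 or any 1 control array (adjusted p from 0.0539 to 0.0793), which left 1 that rose. The list's median of 0.15 and its test differed in sign from its mean of -0.01. That mean includes the targeted gene Nabp2 at -1.68. Of 46 histone genes, 3 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.968). H4c9 and H1f2 rose 2.13-fold and 2.11-fold, and H2ac18 and H2bc4 fell 2.55-fold and 2.31-fold. The number of histone genes that fell was 7 without DKO 1 and 8 without control 3. Of 70 oxidative phosphorylation genes, 2 rose and 2 fell, and adjusted over the list alone 1 and 0 (camera adjusted p = 0.435). Cox7a1 rose 2.13-fold and Cyc1 1.33-fold, while Cox6b2 fell 1.68-fold and Ndufa1 1.41-fold. Cyc1 lost its call without DKO 1, DKO 3, DKO 4, control 1, control 2 or control 4 (adjusted p from 0.0630 to 0.103), Ndufa1 without DKO 2, DKO 4, control 1, control 2 or control 4 (0.0769 to 0.103) and Cox6b2 without control 1 (0.0569) or control 2 (0.0527). Of this list 1 rose without DKO 1, DKO 3, control 1, control 2 or control 4, and 4 fell without DKO 1, 1 without DKO 4 or control 4 and 0 without control 1 or control 2. Alignment by medians gave 0 genes of the complexes that rose and 2 that fell, 0 histone genes that rose and 17 that fell, and 0 oxidative phosphorylation genes that rose. With array weights 9 histone genes and 5 oxidative phosphorylation genes fell. Of the latter 5 rose and 4 fell with no background correction and with the authors' processed values, 4 and 4 with normexp without controls and with a trended and robust variance, and 4 fell with probes detected on all arrays only.

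Of 16 genes of apoptosis and the Bcl2 family, 1 rose and 7 fell, with the same counts adjusted over the list alone. The anti-apoptotic gene Bcl2 fell 3.88-fold by its probe with the highest mean, and 1 of its 5 probes did not pass. Birc2 fell 1.45-fold by one probe while its other probe did not pass, Diablo fell 1.37-fold, and the pro-apoptotic gene Bak1 rose 2.06-fold. The number that fell was 2 without control 1 or control 2, 3 without DKO 2, DKO 4 or control 3 and 4 without DKO 1. Diablo lost its call without DKO 3, control 1, control 2 or control 3 (adjusted p from 0.0517 to 0.0587), and Bak1 without control 1 (0.0558) or control 4 (0.0511), where 0 rose. The list did not pass against other genes (camera adjusted p = 0.386). Of 22 immediate early and stress genes, 2 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0935, and 0.0142 without control 3). Junb rose 2.47-fold and Gadd45a 1.90-fold, while Klf4 and Klf2 fell 6.48-fold and 2.10-fold. Of 15 NF-kB and inflammation genes, 3 rose and 2 fell, and adjusted over the list alone 3 and 3 (camera adjusted p = 0.968). Icam1 rose 1.99-fold and Nfkbiz 1.62-fold, while Tnfaip3, an inhibitor of NF-kB, fell 2.20-fold and Rela 1.35-fold. Rela lost its call without DKO 2 or any 1 control array (adjusted p from 0.0560 to 0.0754), which left 1 that fell, and Nfkbiz without control 2 (0.0683) or control 3 (0.0541), which left 1 that rose. After alignment by medians 0 apoptosis genes rose, 1 immediate early gene rose and 11 fell, and 0 NF-kB genes rose and 5 fell. With probes detected on all arrays only 3 immediate early genes and 1 NF-kB gene fell, and with no filter on dim probes 0 apoptosis genes rose. The median of the NF-kB list, -0.11, differed in sign from its mean of 0.01 and its test.

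**Figure D2:**
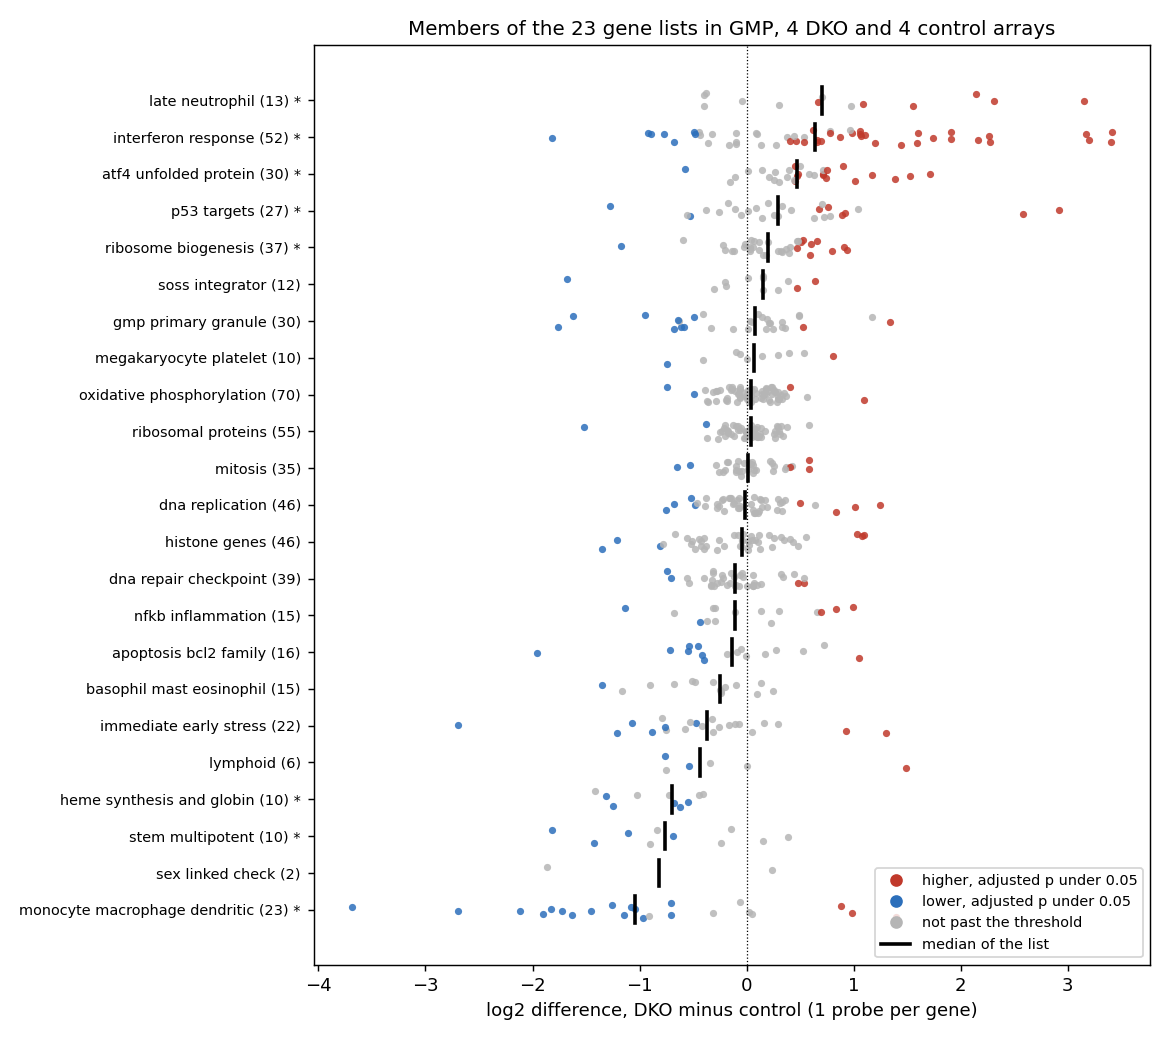
Log2 difference, DKO minus control, of every measured member of the 23 gene lists (horizontal axis), with 1 point per gene, the number of measured genes in brackets, an asterisk at lists past the threshold by camera with the preset correlation, and a bar at each list's median. The medians run from -1.04 for the monocyte, macrophage and dendritic list to 0.70 for the late neutrophil list.

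With the preset correlation, 8 of the 23 lists passed, and with an estimated correlation 0 passed, with a smallest adjusted p of 0.463. Among the list members named, Tgm2, Cdc25b and Tnfaip3 were detected on 1 DKO array, Fanci and Ccl3 on 2, and Klf2, H2ac18 and Vpreb1 on 3, while Ccne2 was detected on 1 control array, Clec1b on 2, and Lig4 and Thy1 on 3. By fry, which tests whether a list's own genes move one way, 9 lists passed.

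Fold sizes and some calls of named genes depended on background and scaling. Of 91 named genes past the threshold, Nabp2 aside, the fold was over 1.5 times smaller for 30 with no background correction, for 30 with the authors' processed values and for 17 with normexp without controls. In all 3 settings these held Oas2, Rsad2, Degs2, Foxd4, Phlda3, Dnmt3l, Klf4, Itgb7, Cpq, Plxdc1, Fbxw4, Ccne2, Stfa1, Ctss, Adgre1, Thy1 and Slc7a11, and in the first 2 also Isg15, Usp18, Irf8, Rdm1, Cdkn1a, H2ac18, Cox7a1, Slc4a1, Clec1b, Bcl2, Tnfaip3, Klf2 and Chac1. Cdc25b, Fanci, Lig4, Ank1, Epor, Kel, Clec1b, Tgm2 and Rag1 lost their calls with no background correction (adjusted p from 0.0672 to 0.150) and with the authors' processed values (0.0698 to 0.158). With normexp without controls Lig4 (0.0967), Ank1 (0.0745) and Rag1 (0.0600) lost theirs. Alignment by medians ended the calls of Mdm2, Ccne1, Rrm2, Aurka, Plk1, Lig4, Ints13, H1f2, H4c9, Rpl29, Noc3l, Mrto4, Ebna1bp2, Cox7a1, Cyc1, Ank1, Clec1b, Anxa1, Rag1, Bak1, Icam1, Nfkbiz, Gadd45a and Mthfd2. With no filter on dim probes Fanci (0.0792), Lig4 (0.0697), Kel (0.0557) and Bak1 (0.0605) did not pass, nor did Lig4 (0.0704) with a trended and robust variance or Fanci (0.0709) with array weights.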

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

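The tests of Y-linked probes and of array quality were chosen only after the missing Xist signal was seen. The 15 values in this part stood far from the other 3 arrays of their group, out of 216 groups of 4 examined, where chance flags about 1 in 20, here 10.8.

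Only 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many probes past the threshold, the real one with 2469, and the highest of the others gave 1. This argues against chance as the source of that count but cannot exclude it, since 1 of 35 is the smallest share possible. Every other split mixed DKO and control arrays, so a difference between the groups would itself keep those counts low.

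The signal of Xist was missing on DKO 3, at a normalized log2 value of 4.39 against 8.40 to 9.20 on the other DKO arrays, and both Xist probes were below detection there. A poor array is argued against, since DKO 3 detected 11103 probes, the most of the DKO arrays. A male animal or a mislabelled sample cannot be told apart from the alternatives: 0 of 7 Y-linked probes were both detected and highest on DKO 3, but 0 arrays are labelled male, so no array shows what these probes read with a Y chromosome, and Uty was detected on 5 arrays labelled female. A single X chromosome also stays open, since the mean of 3 genes that escape X inactivation (Kdm6a, Eif2s3x and Ddx3x) was 9.53 on DKO 3, below the 9.59 to 10.17 of the other DKO arrays but above the 9.51 of control 3. No biological explanation from the design was tested.

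Of 13 late neutrophil genes 6 rose and 0 fell, and of 23 monocyte, macrophage and dendritic genes 15 fell and 3 rose, with list calls lost at adjusted p = 0.569 and adjusted p = 0.463 with an estimated correlation. Mature neutrophils in the DKO sort cannot be told apart from the alternatives: 5 abundant neutrophil transcripts had a median log2 difference of -0.043, but they went both ways (SD 0.63 over transcripts, with Ngp at 0.98), and S100a8 and S100a9 were already at 14.55 and 13.43 in control GMP, where a small share would be hidden. The dim DKO 1 array is argued against for the monocyte list, whose median without it was -1.07, past the threshold with the preset correlation, though on all arrays adjusted p = 0.463 with an estimated correlation. For the late neutrophil list it stays open. Its median without DKO 1 was 0.53 (camera adjusted p = 0.0204). The medians of the 3 other DKO arrays against control were 0.69, -0.023 and 1.29 (SD 0.66). This spread is wider than the distance of 0.53 from the bound of 0.35. That bound was set before this test, but after the rise of the list and the dim array were known. A change in the mix of granulocyte-committed and monocyte-committed cells within the gate, or a change within the same cells, stays open as an untested hypothesis.

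Among genes, Nabp2 was low on control 3, at 8.13 against 8.96 to 9.10 on the other control arrays. Lcn2 was at 8.88 on control 4, Cdkn1a at 7.14 on control 1, Aurka at 10.49 on control 4, H4c9 at 9.46 on control 3, Rpl13a at 12.40 on control 1, Kel at 5.92 on control 2, Csf2ra at 10.25 on control 4 and Stfa1 at 4.52 on control 2. Bak1 was high on control 2, at 7.49, and on DKO 2, at 9.26, and Epor was high on DKO 1, at 5.03. Control 2 was also the brightest array, with a median raw intensity of 153.5 and a mean of 736. The flags fell on control 2 in 5 cases, on control 4 in 3 and on each DKO array in at most 1.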

How the results depend on the processing

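Leaving out DKO 1 and DKO 3 together was chosen after seeing the data. Comparisons of a named gene under an alternative kept the side of the threshold in 1634 cases, lost the call in 136, gained one in 32 and reversed in 2. Direction counted only for genes past the threshold in the main test, so the others may have changed sign. With an estimated correlation the calls of all 8 lists were lost, with adjusted p of 0.535 (interferon), 0.463 (Atf4 and unfolded protein, and monocyte) and 0.569 (p53, ribosome biogenesis, heme, stem and late neutrophil). That setting allows for members that vary together. The estimated correlations of these 8 lists ran from 0.10 (monocyte) to 0.45 (heme), against the preset 0.01. The camera runs differed only in how this correlation was set, so the calls rested on the preset value. By fry, p53 targets lost the call (0.0565), and the lymphoid (0.0469) and apoptosis (0.00752) lists gained one. Over all alternatives the adjusted p ran from 7.08e-15 to 0.535 for interferon, 6.38e-09 to 0.463 for Atf4 and unfolded protein, 1.54e-07 to 0.463 for monocyte, 1.19e-08 to 0.569 for late neutrophil, 0.000265 to 0.569 for ribosome biogenesis, 0.000118 to 0.569 for heme, 0.00125 to 0.569 for p53, 0.00511 to 0.569 for stem, 0.0181 to 0.985 for basophil and 0.0142 to 0.674 for immediate early genes. For the settings named here the cause was not tested, unless given.

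Aligning arrays by medians over all probes, most of them near background, left the median of tested probes at -0.40, and gave 148 higher and 2335 lower probes, 1438 of them past the threshold with quantiles too. There the dimmer Nabp2 probe passed (-0.82), Xrcc4 (-0.059) and Ints5 (-0.039) reversed, the ribosomal protein list passed (8.42e-06) and the stem list did not (0.0537). With no filter on dim probes the stem list lost the call (0.169) and the immediate early list gained one (0.0225). With probes detected on all arrays, which leaves fewer members and removes genes at background in either group, the p53 (0.128), heme (0.117), late neutrophil (0.0751) and monocyte (0.154) lists lost it. Array weights gave -0.80 for the dimmer Nabp2 probe, past the threshold, and 0.0541 for the late neutrophil list. A minimum change of 1.5-fold gave 772 higher and 1012 lower probes, against 308 and 426 with no background correction, 307 and 423 with the authors' processed values, 481 and 662 with normexp without controls, 148 and 2335 with arrays aligned by medians and 656 and 630 with probes detected on all arrays.

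Leaving out each array in turn gave 680 to 1139 higher and 869 to 1333 lower probes, with the lowest counts without control 2 and 745 higher without control 1. Adjusted p ranged from 0.0136 to 0.108 for the stem list (not past without DKO 4, control 1 or control 4), from 0.0228 to 0.949 for the basophil list (past without DKO 3) and from 0.0142 to 0.260 for the immediate early list (past without control 3). The brighter Nabp2 probe ranged from -1.92 to -1.44, and from -2.20 to -1.08 over all alternatives, past the threshold in each. Without DKO 1 and DKO 3 there were 862 higher and 1137 lower probes, and the basophil list passed (0.0181). There 5 ribosome biogenesis genes rose, and 8 heme, 3 apoptosis, 3 immediate early and 4 basophil genes fell.

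The shared replicate numbers gave no clear sign of pairing the samples, but these correlations are too few to exclude it. The correlations of same-numbered deviations were 0.19, 0.03, -0.11 and 0.20. Samples 1 and 4 correlated best with their own number, while 2 and 3 did not. With the replicate block there were 1102 higher and 1318 lower probes, 2189 of them shared, and the stem list was not past the threshold (adjusted p = 0.0821). The slide as a block was not run. Signal over background limits the genes detected on 0 of the 4 arrays of a group, whose changes are bounds.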

Other observations

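The comparison of antigen presentation genes was chosen only after the interferon list was seen, as were its genes, so it tests nothing. The 8 class I antigen presentation genes of the list (B2m, H2-D1, H2-K1, Psmb8, Psmb9, Psmb10, Tap1 and Tapbp) had a median log2 difference of -0.41, with 4 lower and 0 higher past the threshold. The other 44 genes had a median of 0.78, with 28 higher and 3 lower. The difference of medians, -1.18, restates what was seen, and whether the list holds sets of genes that respond differently stays open.

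Genes beside the targeted loci could differ through flanking DNA or altered transcription around Nabp1 and Nabp2. Among the 50 nearest tested genes of each locus, ordered by GRCm38.p6, 28 of 100 passed the threshold, against 1822 of 7501 others, an odds ratio of 1.21 (95% interval 0.75 to 1.91, Fisher's exact test, two-sided, p = 0.411). The interval leaves both a modest excess and none open. Each locus had 14 such neighbours. Over the 20 chromosomes tested, the share of genes past the threshold ran from 21.4% to 28.2%, and after adjustment over chromosomes 0 stood apart, with a smallest adjusted p of 0.426 by Fisher's exact test.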
